A study of Drosophila melanogaster with 21 samples.

How the data were processed

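Poly-A RNA was sequenced from wing imaginal discs of male Drosophila melanogaster larvae. Per the labels, the larvae were in the third larval instar and were reared at 25 °C, RNA was extracted with TRIzol and a Direct-zol kit, and libraries were made with a TruSeq Stranded mRNA kit. The deposited table holds raw read counts per FlyBase gene, with 1 column for each of the 21 libraries and no normalisation. The values were checked to be whole numbers with a different total in every column, and no 2 columns were identical. The submitters' notes name STAR 2.6.1b, featureCounts of Subread 1.6.1, SAMtools 1.9, deepTools 3.1.2, FastQC 0.11.7, MultiQC 1.6 and DESeq2 1.18.1, and the builds dm6 and BDGP6. The strand setting of the counting and the annotation release are not given in the sources used here. Counts of genes that overlap, of antisense genes and of close paralogs (the GstD and GstE clusters, the Hsp70 copies, Stellate repeats) are therefore uncertain where reads could be shared between them.

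Genes were matched by FlyBase identifier to the reference annotation of dm6 for chromosome, start, end and exon length. Of 17558 genes in the table, 17252 were matched, and the 306 unmatched genes held 5.53% of all counts. Unmatched genes stayed in the tests over all genes but were left out of every analysis by chromosome. No reads were counted in any library for 784 genes. Total counts ran from 830905 to 4131600 per library (median 2458046). These totals limit the precision of weakly expressed genes: 3 counts, the limit that a count of 0 allows, was the floor used for fold changes against groups with no counts. The floor covers counting error only.

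Differential expression was tested with edgeR 4.0.16 in R 4.3.3, with robust quasi-likelihood fits of 1 mean for each of the 7 groups over all 21 libraries. Genes passed filterByExpr with the groups, which left 11420 genes, 1669 of them on the X and 9388 on chromosomes 2 and 3. TMM scaling factors were computed on genes of the arms 2L, 2R, 3L and 3R, so that a shift of the whole X would not enter the scaling. p values were adjusted by Benjamini-Hochberg over the genes tested, and a gene was called changed at an adjusted p under 0.05. Each mutant with heterozygous siblings of its own stock was compared with those. The labels give the roX1 roX2 mutants no control of their own, so the mean of the 3 heterozygous group means served as their control, and their comparison shares control libraries with the other 3. Adjusted p values of genes in all texts are edgeR's unless another tool is named, errors of log2 fold changes are standard errors derived from the same test (the log2 fold change over the root of F), and CPM values use the same scaling factors.

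The X was compared with the autosomes as the median log2 fold change of X genes minus that of genes on chromosomes 2 and 3, a value that scaling of libraries moves little (TMM on all genes took it from -0.161 to -0.149 in msl-1 mutants and moved it less in the others). It was tested between libraries by exact two-sided permutation of values per library (log2 CPM with a prior count of 2), within each comparison and, for the msl-2, msl-1 and mle stocks together, with labels permuted within each stock. It was also tested across genes with camera in limma 3.58.1, at the preset correlation of 0.01 and with an estimated correlation. Genes are not independent replicates, so the camera p values are given beside the tests between libraries.

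The gene lists were fixed before the data were examined: the MSL complex, chromatin factors linked to dosage compensation, wing patterning, leg and haltere discs, apoptosis, JNK signalling and regeneration, heat shock and unfolded protein response, detoxification, ecdysone response, cuticle, cytoplasmic ribosome, oxidative phosphorylation, glycolysis, cell cycle, DNA damage response, immunity, sex determination, Y-linked genes, autosomal pericentric genes, and markers of adult muscle precursors, larval muscle, fat body, hemocytes, trachea, neurons and glia, salivary gland, gut, and germline and testis. Lists with at least 5 tested members were tested with camera, at both correlations, and with fry, adjusted over the lists within a comparison. Named genes followed a rule also fixed before: genes of the MSL complex. Then came up to 5 X-linked and 5 autosomal genes with the lowest and with the highest log2 fold change, among called genes with a mean of at least 5 CPM whose mutant libraries all lay beyond all control libraries. Up to 4 members per list with the smallest adjusted p were named as well. For genes called in all 4 comparisons, the rule named the 5 autosomal genes higher and the 5 lower with the largest mean size. For differences between mutants and between heterozygous groups it named up to 5 genes with the smallest p.

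Heterozygous msl-1 replicate 2 stood apart from all other libraries. The counts and tests of the main fit were therefore repeated without it, in 20 libraries and 10367 genes. This alternative was chosen after seeing the data for the msl-2 and mle comparisons and for leading counts of the lists. For msl-1 and roX1 roX2 it was planned before as part of leaving out each library in turn. Of the alternatives below, the other TMM scalings, DESeq2 and the replicate block were also run without it. Other filters, the mean and limma voom were not. The value over all 21 libraries stays the reported one, with the 20-library value beside it.

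Other alternatives fixed before were TMM on all genes or on chromosome 3 genes, DESeq2 1.42.0 with its own size factors, no filter or other filters on low counts, only the groups compared in the fit, the replicate number as a block, chromosome 3 as the autosomal reference, the mean in place of the median, other control groups, and a minimum fold change of 1.5. limma voom with library weights was added after seeing the data. TMM on all genes and only the groups compared were fixed before for counts of changed genes and were added after seeing the data for X minus autosome of each mutant against heterozygous discs, as were DESeq2 and the replicate block in 20 libraries and the stratified test with 1 library left out. The pipeline was tested on simulated data with the same library sizes and spread. Of genes simulated with a 2-fold change, it recovered between 4.48% and 26.9% per comparison at the spread of all 21 libraries and between 38.8% and 61.2% at the spread of 20. A simulated X shift of -0.40 was recovered as -0.38 to -0.41. Figures were drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.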

Results

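The data are messenger RNA profiles of wing imaginal discs, the larval tissue that gives rise to the adult wing, from male fruit flies mutant or heterozygous for parts of the MSL complex. This complex of proteins and non-coding RNAs binds the X of males and raises its transcription. By the labels, mutant males carried mutations of msl-2 (4 libraries), msl-1 (3 libraries), mle (3 libraries), or both roX1 and roX2 (3 libraries). msl-1 and msl-2 encode the core that assembles the complex, mle encodes an RNA helicase, and roX1 and roX2 are X-linked long non-coding RNAs that are part of it. Controls were males heterozygous for the msl-2 (3 libraries), msl-1 (3 libraries) or mle (2 libraries) mutation over the CyO-GFP balancer, a rearranged second chromosome with a GFP marker. The series asks how X-linked and autosomal expression respond to the loss of dosage compensation.

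Total counts ran from 2690455 to 3451256 in msl-2 heterozygous libraries, from 830905 to 2042014 in msl-1 heterozygous libraries and from 3013611 to 3774192 in mle heterozygous libraries. They ran from 2458046 to 2763656 in msl-2 mutants, 1388848 to 2377847 in msl-1 mutants, 1659482 to 2483435 in mle mutants and 1972761 to 4131600 in roX1 roX2 mutants. Heterozygous msl-1 replicate 2 had the lowest total and stood apart: reads were counted for 16540 genes, mitochondrial genes held 6.17% of its counts against 1.13% to 2.54% in the other heterozygous libraries, and its median correlation with its own group was 0.552. Leaving it out lowered the common biological coefficient of variation from 0.362 to 0.210. Values over all 21 libraries come first below, and 20-library values, without that library, follow where they differ in call or size.

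The targeted genes were read first. roX2 (X, 11579065 to 11580432) fell from 297 ± 24.4 CPM (SD, n = 3) in msl-2 heterozygous discs to 2.61 ± 1.06 (SD, n = 4) in msl-2 mutants, and from 326 ± 74.1 (SD, n = 2) to 2.25 ± 0.835 (SD, n = 3) in mle mutants. In msl-1 it fell from 108 ± 82.2 (SD, n = 3) to 0.458 ± 0.408 (SD, n = 3). No roX2 read was counted in the 3 roX1 roX2 mutant libraries, which puts roX2 at least 645-fold lower than in the heterozygous groups with a floor of 3 counts over the group. roX1 (X, 3857230 to 3862697) was at 50.5 ± 17.7 CPM (SD, n = 3) in roX1 roX2 mutants, 131 ± 16.0 (SD, n = 3) in msl-1 mutants and 104 ± 36.2 (SD, n = 3) in mle mutants, against 2711 ± 77.4 (SD, n = 3) and 3721 ± 36.8 (SD, n = 2) in msl-2 and mle heterozygous discs. In msl-1 heterozygous discs it was at 2426 ± 1650 (SD, n = 3), from 525.6 to 3433. In msl-2 mutants roX1 stayed at 1740 ± 155 CPM (SD, n = 4), a log2 fold change of -0.64 ± 0.44 that did not pass (adjusted p = 0.522), and that passed in 20 libraries at -0.60 ± 0.19 (adjusted p = 0.0470).

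The transcripts of the mutated protein genes did not all fall. msl-2 (2L, 3462218 to 3466112) went from 104 ± 8.69 CPM (SD, n = 3) to 54.7 ± 4.18 (SD, n = 4) in its mutant (adjusted p = 0.0143). msl-1 (2L, 18683720 to 18688800) rose from 69.5 ± 40.7 (SD, n = 3) to 135 ± 19.8 (SD, n = 3) in its mutant (log2 0.96 ± 0.29, adjusted p = 0.0180), a call that missed in 20 libraries (log2 0.63 ± 0.23, adjusted p = 0.0504). mle (2R, 5974857 to 5980778) was at 147 ± 0.424 (SD, n = 2) and 234 ± 14.0 (SD, n = 3), log2 0.67 ± 0.22 with adjusted p = 0.110 in 21 libraries and 0.70 ± 0.14 with adjusted p = 0.00151 in 20. The other members of the complex, msl-3 and mof, which encode a chromodomain protein and a histone H4 acetyltransferase, passed in none of the 4 comparisons. Over the MSL complex list of 7 genes, 2 fell in each comparison, roX2 with msl-2 in msl-2 mutants and with roX1 in the others, and 1 rose in msl-1. Adjusted over the list alone, 2 fell in each of the 4 comparisons and 1 rose in msl-1 and in mle. In 20 libraries 3 were lower in msl-2 and 1 higher in mle. The list holds the mutated genes themselves, and in roX1 roX2 mutants the 2 that fell are the mutated ones. A camera test of it restates the genotype in part and is not read here. In msl-1 over all 21 libraries the list's median was 0.13 and its mean -1.495.

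**Figure D1:**
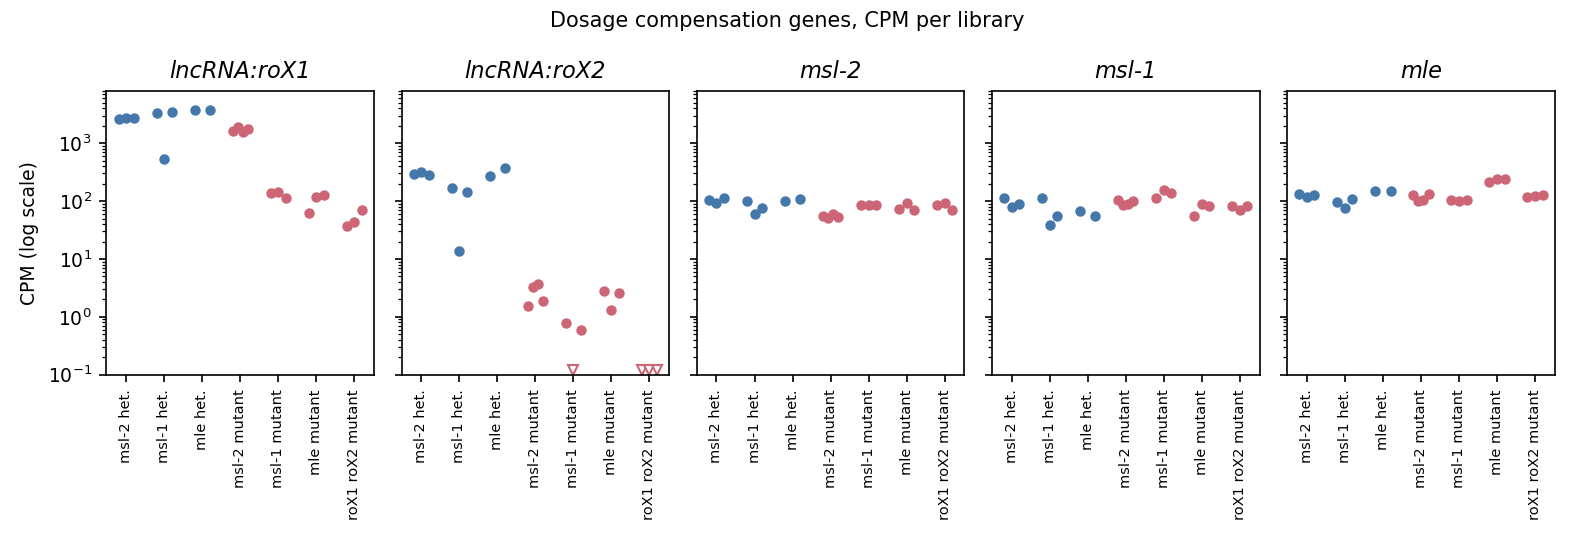
Normalised expression (CPM, log axis) of roX1, roX2, msl-2, msl-1 and mle in each library, by group; each point is a library, blue for heterozygous and red for mutant, and open triangles at the bottom mark a count of 0. roX2 was at 0 in the 3 roX1 roX2 and in 1 of the 3 msl-1 mutant libraries, and roX1 stayed between 1585 and 1936 CPM in the 4 msl-2 mutant libraries.

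Genes on the X were lower relative to autosomal genes in all 4 mutants by the median over filtered genes. With msl-1 heterozygous replicate 2 kept, the direction in msl-1 and roX1 roX2 mutants depended on the processing. In msl-1 mutants X minus autosome was 0.30 without a filter, 0.45 with a CPM of at least 1 in 3 libraries and 0.068 with the mean, and in roX1 roX2 mutants it was 0.02 against msl-1 heterozygous discs alone. Without that library, mean values per library were -0.536 in msl-1 and -0.341 in roX1 roX2 mutants, against -0.155 in msl-1 heterozygous discs. The other filters and the mean were not run without it. The median X gene fell to 76.5% of its heterozygous level relative to the autosomes in msl-2 mutants (X minus autosome log2 -0.39), to 66.9% in mle mutants (-0.58), to 83.7% in roX1 roX2 mutants (-0.26) and to 89.4% in msl-1 mutants (-0.16), over 1669 X genes. In 20 libraries the values were 77.2%, 66.3%, 78.4% and 76.6% over 1560 X genes. Between libraries, the 4 msl-2 mutant libraries (mean -0.20 ± 0.05 SD) lay below the 3 heterozygous ones (0.16 ± 0.02 SD), with an exact permutation p = 0.0286, the smallest that 35 splits allow. The 3 mle mutant libraries (-0.39 ± 0.03 SD) lay below both of theirs (0.16 ± 0.01 SD), with an exact permutation p = 0.10, the smallest possible for 3 against 2. The exact permutation p was 1.00 for msl-1 and 0.333 for roX1 roX2 over all libraries, and in 20 libraries every mutant library lay below every control, with p = 0.10 and 0.00833, the smallest possible. The roX1 roX2 test pools control libraries of 3 other stocks. These stocks differed in X minus autosome themselves (msl-1 minus mle heterozygous discs -0.27 in 20 libraries), so its p measures stock as well as genotype. Permuted within the 3 stocks together, the difference was -0.32 (exact permutation p = 0.0113, 7000 splits), and -0.44 in 20 libraries (exact permutation p = 0.000286, 3500 splits). Without mle heterozygous replicate 1 or 2 it was -0.19 or -0.18, and the exact permutation test did not pass. These fits kept msl-1 heterozygous replicate 2 and set the expression filter again with a lone mle control. Without mle heterozygous replicate 2 the shift in mle mutants was still -0.50, while msl-1 minus mle went from 0.46 to 0.76. The loss therefore cannot be read as dependence on the mle controls alone. What the filter added was not tested.

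The shift was spread over the chromosome, and in the lowest expression class it was absent in some comparisons. With the X divided into 1 Mb bins, 23 of 23 bins with at least 20 genes had a median below 0 in mle and in roX1 roX2 mutants, 22 of 23 in msl-2 and 19 of 23 in msl-1 mutants, and 23 of 23 in msl-1 mutants in 20 libraries. With X genes divided into 3 classes of expression, X minus autosome in the highest class was -0.34 in msl-2, -0.40 in msl-1, -0.68 in mle and -0.38 in roX1 roX2 mutants. In the lowest class it was -0.39, 0.48, -0.34 and 0.07 in msl-2, msl-1, mle and roX1 roX2 mutants over all libraries, and -0.51, -0.05, -0.38 and -0.17 in 20. Across genes, a test beside the exact permutation tests between libraries, camera called the X lower in all 4 comparisons, with p = 4.61e-12 for msl-2, 0.0491 for msl-1, 1.62e-23 for mle and 2.10e-07 for roX1 roX2. With an estimated correlation the camera p values, again beside the exact tests, were 0.0153, 0.424, 0.00138 and 0.0610, and in 20 libraries 1.72e-06, 0.000115, 3.83e-08 and 8.76e-06. The camera call in msl-1 mutants, where the exact permutation p was 1.00, was lost without mutant replicate 2 (X minus autosome -0.15, camera p = 0.0561), heterozygous replicate 1 (-0.03, camera p = 0.534) and heterozygous replicate 3 (-0.12, camera p = 0.219). The fourth chromosome had medians of -0.02, -0.12, -0.16 and -0.07 in msl-2, msl-1, mle and roX1 roX2 mutants, and camera did not call it in any of them over all 21 libraries. In 20 libraries its median in msl-1 mutants was -0.38 (camera p = 0.0333 across genes, a call lost with an estimated correlation, p = 0.378, with no exact test run for this chromosome).

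**Figure D2:**
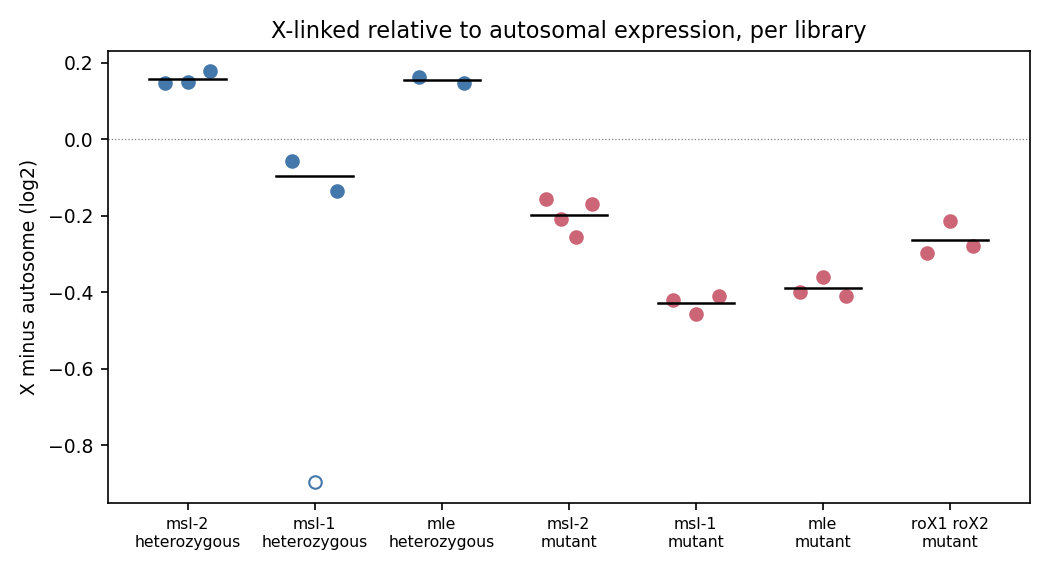
X minus autosome value (log2) of each of the 21 libraries, by group, with heterozygous groups in blue, mutants in red and black lines for group means; the open circle is msl-1 heterozygous replicate 2, which the mean line leaves out. That library lies at -0.90, and the other 7 heterozygous libraries lie between -0.13 and 0.18.

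**Figure D3:**
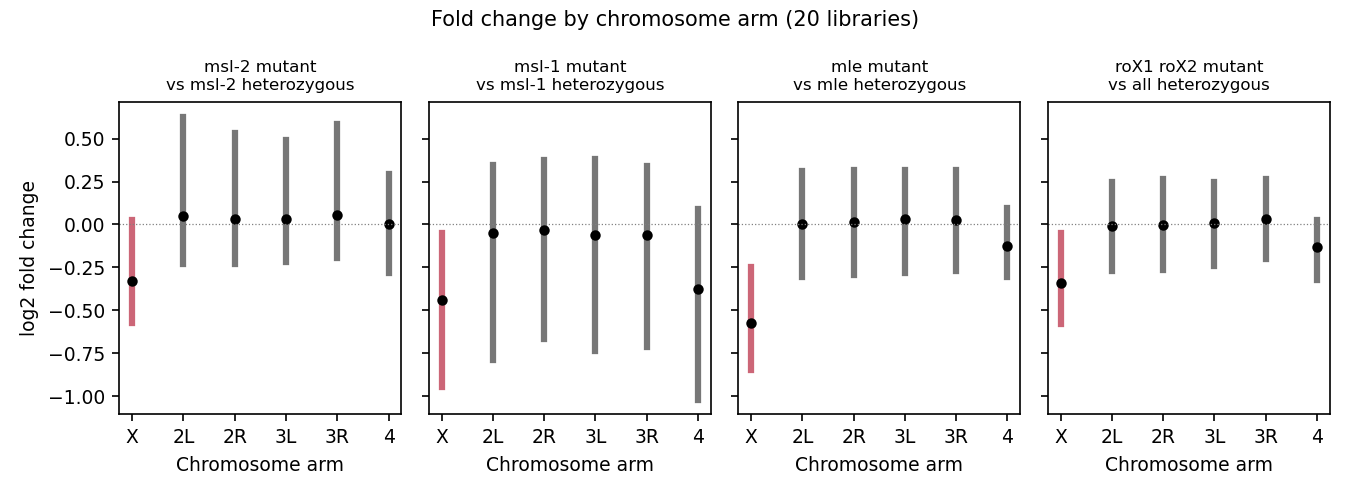
Log2 fold change by chromosome arm in each comparison, in 20 libraries; points are medians over the genes of an arm and bars span the quartiles. The X medians are -0.33 in msl-2, -0.44 in msl-1, -0.57 in mle and -0.34 in roX1 roX2 mutants, and the medians of the arms 2L, 2R, 3L and 3R lie between -0.06 and 0.06.

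In msl-2 mutants few genes passed the threshold over all libraries. On the X, w, which encodes an ABC transporter for eye pigment precursors (X, 2790599 to 2796466), was lower by log2 -6.38 ± 0.43, and CG3097, CBP and CG14439 fell by between -1.54 ± 0.32 and -1.83 ± 0.43. w fell in all 4 mutants (-6.20 in msl-1, -6.25 in mle and -5.03 in roX1 roX2), far more than the median X gene. The sample titles give no w genotype, so its fall is not read as an effect of dosage compensation. CG15784 rose (4.09 ± 0.36), as did CG32625 (3.68 ± 0.82), CG2909 (1.79 ± 0.30) and Nt5b (1.03 ± 0.24). On the autosomes, St2, a sulfotransferase gene, fell (-3.76 ± 0.72), with wbl (-2.82 ± 0.66), CG9416 (-2.63 ± 0.59), the small heat shock gene Hsp67Ba (-2.50 ± 0.39) and CG6287 (-2.50 ± 0.50). CG14695 (6.38 ± 0.92), CR43086 (4.18 ± 0.98), the glutathione transferase gene GstE6 (4.16 ± 0.55), CG11893 (4.08 ± 0.80) and Arc1 rose. CG11893 was at 39.6 CPM in mutant replicate 2 and at 10.3 to 12.9 in the other mutant libraries. Arc1 (2R, 14357927 to 14360297), whose protein forms capsids that carry RNA between cells, rose by 4.11 ± 0.59 (n = 4 against 3).

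In total 64 genes were higher and 74 lower in msl-2 mutants over all 21 libraries, with 1479 genes at an unadjusted p under 0.05. In 20 libraries 318 were higher and 790 lower, with DESeq2 475 and 685. Of the lower genes, 25.7% were X-linked in 21 libraries and 49.0% in 20, against 14.6% and 15% of the genes tested. The count fell to 25, 32, 78 and 39 without msl-2 heterozygous replicate 1, heterozygous replicate 2, mutant replicate 1 and mutant replicate 2. Of 18 DNA damage response genes 4 rose and 0 fell: Ku80 (1.19 ± 0.20) and Irbp (1.23 ± 0.21), which encode the Ku heterodimer that binds broken DNA ends, and rad50 (1.04 ± 0.22) and mre11 (1.01 ± 0.22) of the MRN complex. Adjusted over the list alone the count was also 4, and camera called the list higher (adjusted p = 0.00131; adjusted p = 0.416 with an estimated correlation). Of 25 detoxification genes 2 rose, GstE6 and GstE5 (2.07 ± 0.44), and 4 adjusted over the list alone, and 4 rose and 3 fell in 20 libraries (camera adjusted p = 0.0186, and 0.416 with an estimated correlation). Of 23 ecdysone response genes 2 fell, the nuclear receptor genes Eip78C (-2.27 ± 0.39) and Hr4 (-3.51 ± 0.82), and adjusted over the list alone 9 fell and 1 rose, and 5 fell in 20 libraries (camera adjusted p = 0.00206, and 0.416 with an estimated correlation). Of 26 genes of JNK signalling and regeneration, chinmo (3.54 ± 0.70), Irbp18 (1.34 ± 0.30) and Gadd45 (1.26 ± 0.31) rose and chrb (-1.23 ± 0.31) fell, and adjusted over the list alone 4 rose and 3 fell, and 5 rose and 4 fell in 20 libraries (camera adjusted p = 0.470). No gene of the wing patterning list passed over all 21 libraries (43 tested). In 20 libraries hth (-0.53 ± 0.14), bs (-0.57 ± 0.18) and tsh (-0.38 ± 0.12) fell and aos (0.61 ± 0.18) rose, named after their values were seen.

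Few markers of larval muscle and fat body passed in msl-2 mutants. Of 19 larval muscle genes, sls, which encodes a giant muscle protein, rose (2.52 ± 0.48), and camera called the list higher (adjusted p = 0.0172, and 0.930 with an estimated correlation); adjusted over the list alone the count was also 1, and 2 rose in 20 libraries. None of 12 fat body genes passed over all genes, 1 rose in 20 libraries and 8 were higher adjusted over the list alone, with the larval serum protein gene Lsp2 at 6.02 ± 1.59 (adjusted p = 0.0916) and a list median of 2.90 (camera adjusted p = 0.0263, and 0.893 with an estimated correlation).

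In msl-1 mutants more genes changed than in any other mutant in the fits of all 21 and of 20 libraries. With only the groups compared in the fit msl-1 was not first, with 442 genes against 1218 in msl-2 and 829 in mle mutants. Arc1 rose by 7.75 ± 0.70, from 36.7 to 7878 CPM, and Ilp8 (3L, 17029812 to 17032080), an insulin-like peptide that damaged discs secrete to delay metamorphosis, rose by 6.86 ± 0.93 (n = 3 against 3; 9.57 ± 1.2 in 20 libraries). upd1, a ligand of JAK/STAT signalling, rose by 2.94 ± 0.33, and Socs36E, a target of that pathway, by 2.55 ± 0.37. GstE6 (5.74 ± 0.57), Cpr47Ec (5.15 ± 1.53, and 6.23 ± 2.05 in 20 libraries) and CG3397 (4.83 ± 0.75, and 5.97 ± 1.01) rose on the autosomes, and CG32625 (6.11 ± 0.89, and 6.71 ± 1.29), CG15784 (4.49 ± 0.37), CG15047 (3.57 ± 0.79, and 5.06 ± 0.86) and CG2909 (3.06 ± 0.32) on the X. ImpE2, an ecdysone-inducible gene, fell from 1462 to 0.357 CPM (-11.68 ± 2.61), and no St2 read was counted in the mutants, at least 65.4-fold lower with a floor of 3 counts over the group. Obp99a (-6.29 ± 1.12), CG12828 (-6.00 ± 1.39) and CG9896 (-5.95 ± 0.80, and -5.29 ± 0.76 in 20 libraries) fell as well. On the X, w (-6.20 ± 0.53), Nep3 (-4.28 ± 1.01) and the T-box gene org-1 (-3.68 ± 0.92) fell. org-1 did not pass in 20 libraries (-2.03 ± 0.82, adjusted p = 0.0766), where Nep3 fell under the expression filter.

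Of 43 wing patterning genes, 15 were lower and 3 higher in msl-1 mutants, also 15 and 3 adjusted over the list alone, and 25 did not pass. Lower genes made up 25.4% of all genes tested there. In 20 libraries 26 of the 43 were lower and 2 higher, with 12.7% of all genes lower. The homeobox genes Dll (-3.81 ± 0.36) and al (-3.48 ± 0.36), the Collier gene kn (-2.90 ± 0.42) and pdm2 (-2.45 ± 0.36) were among them. Camera called the list lower (adjusted p = 0.00284, and 0.602 with an estimated correlation). Of 11 genes of leg and haltere discs, which include Dll and al, 7 fell and 0 rose, with B-H1 (-3.32 ± 0.58) and dac (-2.39 ± 0.53, and -1.49 ± 0.45 in 20 libraries), and 8 fell adjusted over the list alone (camera adjusted p = 0.000111, and 0.0280 with an estimated correlation).

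Members of the DNA damage response and JNK lists were called higher more often than lower in msl-1 mutants, where 12.8% of all genes tested were higher and 25.4% lower. Of 18 DNA damage response genes 11 rose and 2 fell, over all genes and adjusted over the list alone, with Ku80 at 2.57 ± 0.22, rad50 at 2.55 ± 0.24, mre11 at 2.47 ± 0.24 and Irbp at 2.33 ± 0.23 (camera adjusted p = 3.50e-08, and 0.0505 with an estimated correlation; 0.0524 in 20 libraries). Of 26 genes of JNK signalling and regeneration 14 rose and 4 fell, also 14 and 4 adjusted over the list alone, with Gadd45 (3.57 ± 0.35) and Irbp18 (2.46 ± 0.33), a partner of the stress factor Xrp1 (camera adjusted p = 6.72e-07, and 0.0454 with an estimated correlation; 0.0550 in 20 libraries). Of 16 apoptosis genes 6 rose and 2 fell: p53 (1.97 ± 0.27), rpr (2.04 ± 0.39) and hid (0.98 ± 0.24) rose, and the TNF receptor gene wgn fell (-1.60 ± 0.28). Adjusted over the list alone 7 rose and 2 fell (camera adjusted p = 0.0113, and 0.404 with an estimated correlation). Of 25 detoxification genes 7 rose and 3 fell, also 7 and 3 adjusted over the list alone, among them GstD3 (2.68 ± 0.36), GstE5 (3.48 ± 0.46) and Cyp12d1-p (-2.72 ± 0.52), with camera adjusted p = 0.00330, and 0.221 with an estimated correlation. Of 23 ecdysone response genes 14 fell and 3 rose, 16 and 3 adjusted over the list alone: the protease genes Np (-2.48 ± 0.31) and Sb (-3.04 ± 0.51) fell, and Ldh (2.88 ± 0.54) and ImpL2 (1.97 ± 0.39), a secreted antagonist of insulin signalling, rose (camera adjusted p = 0.00510, and 0.404 with an estimated correlation).

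The msl-1 comparison gave 1457 genes higher and 2903 lower over all 21 libraries (5739 at an unadjusted p under 0.05) and 1081 and 1313 in 20. The count was 6599 without heterozygous replicate 1, and 2602, 1696 and 2769 without mutant replicate 1, 2 and 3. Of the lower genes, 13.2% were X-linked in 21 libraries and 30.1% in 20. DESeq2 size factors moved the median of all genes by -0.122 relative to the reported scaling.

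Against heterozygous discs of the same stock, mle mutants had the largest fall of the X (-0.58). With all heterozygous groups as control the order changed, with X minus autosome at -0.45 in msl-1, -0.40 in mle and -0.20 in msl-2 mutants. X values of the libraries themselves were lowest in msl-1 mutants (mean -0.43, against -0.39 in mle mutants). On the X, w (-6.25 ± 0.51), the ecdysone-induced receptor gene Hr4 (-4.02 ± 0.98) and spirit (-3.76 ± 0.75) fell, and CG32625 (5.69 ± 1.07), CG15784 (4.99 ± 0.45), CG15047 (4.49 ± 0.97), Nt5b (2.24 ± 0.30) and CG2909 (2.23 ± 0.34) rose (n = 3 against 2). On the autosomes the serpin gene Spn100A (-7.74 ± 1.77), CG15905 (-5.66 ± 1.11), St2 (-4.82 ± 0.92), lncRNA:CR44701 (-4.76 ± 0.93) and Blimp-1, an ecdysone-induced repressor (-4.53 ± 0.97), fell. Arc1 (7.60 ± 0.85), CG43120 (6.52 ± 0.99), Ilp8 (6.37 ± 1.2), CG14695 (6.32 ± 0.84) and GstE6 (5.42 ± 0.67) rose.

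In mle mutants 6 of 18 DNA damage response genes rose and 0 fell, and 7 rose adjusted over the list alone: Irbp (2.29 ± 0.26), Ku80 (1.95 ± 0.25), mre11 (1.71 ± 0.27) and rad50 (1.67 ± 0.27) were the 4 with the smallest p (camera adjusted p = 5.24e-12, and 0.0434 with an estimated correlation; 0.0746 in 20 libraries). Of 26 genes of JNK signalling and regeneration 6 rose and 0 fell, 8 and 3 adjusted over the list alone and 9 and 3 in 20 libraries, with Gadd45 (3.10 ± 0.40), Xrp1 (1.85 ± 0.40) and Irbp18 (1.61 ± 0.36); camera adjusted p = 9.10e-05, and 0.143 with an estimated correlation. Of 25 detoxification genes 4 rose, 5 adjusted over the list alone, among them Gclc (1.33 ± 0.22), which encodes the catalytic subunit of the enzyme that starts glutathione synthesis (camera adjusted p = 0.00338, and 0.150 with an estimated correlation). Of 23 ecdysone response genes 6 fell, with Np (-1.66 ± 0.30), Sb (-2.57 ± 0.49) and Eip78C (-1.96 ± 0.43); adjusted over the list alone 11 fell and 1 rose, and 10 fell in 20 libraries (camera adjusted p = 5.45e-05, and 0.150 with an estimated correlation). Of 43 wing patterning genes al (-2.06 ± 0.31), bs (-1.32 ± 0.29) and Dll (-1.28 ± 0.32) fell, 4 adjusted over the list alone, and 14 fell in 20 libraries (camera adjusted p = 4.09e-06, and 0.328 with an estimated correlation). In the list of leg and haltere discs al and Dll were the 2 of 11 that fell, 3 adjusted over the list alone and 3 in 20 libraries (camera adjusted p = 0.0515, and 0.256 with an estimated correlation). Of 16 apoptosis genes p53 rose (1.09 ± 0.30) and wgn fell (-1.24 ± 0.28), also 1 and 1 adjusted over the list alone, and 2 rose and 3 fell in 20 libraries (camera adjusted p = 0.713).

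The mle comparison gave 158 genes higher and 225 lower over all 21 libraries (1505 at an unadjusted p under 0.05), and 421 and 929 in 20. Of the lower genes, 48.0% were X-linked in 21 libraries and 60.4% in 20. With TMM on all genes 51.6% of the calls were higher, against 41.3% as reported, and the median of all genes moved by 0.109. DESeq2 gave 634 higher and 832 lower in 20 libraries. The count was 30 and 139 without mle heterozygous replicate 1 and 2, each of which leaves a lone control library, and 226 and 153 without mutant replicate 1 and 2.

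Several of these genes changed in males without roX1 and roX2 too. Arc1 (6.23 ± 0.46), CG15784 (4.40 ± 0.26) and CG32625 (5.04 ± 0.62) rose, and w (-5.03 ± 0.41) and CG15905 (-5.07 ± 0.97) fell (n = 3 against 8). ppk13 (2L, 21086790 to 21088751; 5.85 ± 0.25) and its neighbour CG33509 (2L, 21084605 to 21086506; 5.84 ± 0.40) rose together, with CG31601 (6.21 ± 0.45) and lncRNA:CR44316 (7.67 ± 0.68, and 8.26 ± 0.65 in 20 libraries) on chromosome 2 and Reepl1 (6.06 ± 0.67), Erk7 (4.98 ± 0.62) and OtopLa (4.17 ± 0.42) on the X. ppk13 (4.07 ± 0.30) and CG33509 (3.99 ± 0.47) rose in msl-1 mutants as well. ppk13 belongs to the family of degenerin and epithelial sodium channels. CG11695, which ends at 11578806 on the X beside roX2, fell by -6.61 ± 0.49. CG3823 (-3.88 ± 0.72), CR40190 (-5.52 ± 0.66), the aminopeptidase gene SP1029 (-3.37 ± 0.75) and Spn42De (-3.21 ± 0.49) fell, and lncRNA:CR44701 had no counts in the mutants, at least 33.0-fold lower with the floor of 3 counts over the group. CG3823 and lncRNA:CR44701 fell in all 4 mutants.

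In roX1 roX2 mutants 7 of 18 DNA damage response genes rose and 0 fell, 8 adjusted over the list alone: Ku80 (2.50 ± 0.16), Irbp (1.84 ± 0.17), mre11 (1.66 ± 0.18) and rad50 (1.55 ± 0.18) led the list (camera adjusted p = 2.83e-14, and 0.0183 with an estimated correlation). Of 26 genes of JNK signalling and regeneration 6 rose and 1 fell, 7 and 1 adjusted over the list alone and 10 and 3 in 20 libraries, with Gadd45 (2.72 ± 0.25), chinmo (3.16 ± 0.51), Irbp18 (1.74 ± 0.24) and Xrp1 (1.59 ± 0.26); camera adjusted p = 0.000245, and 0.130 with an estimated correlation. Of 25 detoxification genes 6 rose, with GstE6 (4.61 ± 0.40), GstD3 (2.65 ± 0.30), GstE8 (2.91 ± 0.52) and Gclc (1.16 ± 0.15), and adjusted over the list alone 7 rose and 1 fell (camera adjusted p = 4.55e-05, and 0.0566 with an estimated correlation). Of 23 ecdysone response genes 6 fell, with Eip78C (-1.82 ± 0.36), Np (-1.15 ± 0.24), Blimp-1 (-3.60 ± 0.84) and Hr4 (-3.64 ± 0.88), and 8 adjusted over the list alone and 9 in 20 libraries (camera adjusted p = 0.000440, and 0.169 with an estimated correlation). al (-1.26 ± 0.25) was the single wing patterning gene and the single gene of the leg and haltere list that fell over all genes. Adjusted over the list alone, 1 of 43 and 2 of 11 fell, with camera adjusted p = 0.0151 and 0.00509, and 0.868 and 0.0766 with an estimated correlation. In 20 libraries 10 wing patterning genes fell and 1 rose. There 3 of the leg and haltere list fell.

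Of 10 digestive enzyme genes of the gut list, 5 rose, 1 fell and 4 did not pass in roX1 roX2 mutants, and 7 rose and 1 fell adjusted over the list alone, with the protease genes Jon65Aiii (9.74 ± 1.65), Jon65Aiv (9.14 ± 1.54) and alphaTry (7.27 ± 1.33) higher and LManII (-2.92 ± 0.40) lower. Camera did not call the list (adjusted p = 0.415). In 20 libraries the list had fewer than 5 members past the expression filter and was not tested. Most of the 10 genes therefore passed the filter only with msl-1 heterozygous replicate 2 included. In how many mutant libraries the protease genes rose was not examined, so these rises may rest on few libraries.

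The roX1 roX2 comparison gave 389 genes higher and 220 lower over all 21 libraries (1800 at an unadjusted p under 0.05), and 706 and 784 in 20. Of the lower genes, 33.2% were X-linked in 21 libraries and 51.5% in 20. The count was 262 without mle heterozygous replicate 1, and 364 and 329 without mutant replicate 2 and 3. X minus autosome was 0.02 against msl-1 heterozygous discs alone, -0.44 against msl-2 and -0.42 against mle heterozygous discs alone.

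**Figure D4:**
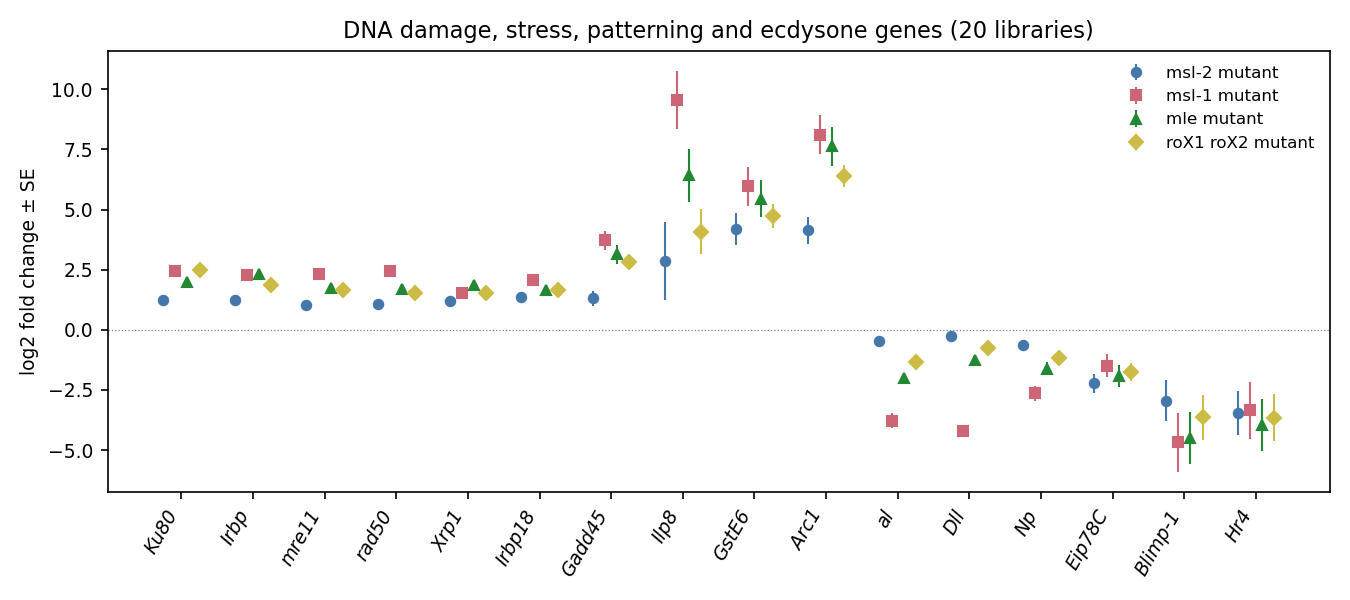
Log2 fold changes of genes of DNA damage response, stress, patterning and ecdysone response in the 4 mutants, in 20 libraries; symbols stand for the mutants and bars for standard errors. Ku80, Irbp, mre11 and rad50 lie above 0 in each mutant, and Dll lies at -4.21 in msl-1 and at -0.25 in msl-2 mutants.

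Genes changed in the same direction in all 4 mutants numbered 45 higher and 33 lower over all 21 libraries, and 115 higher and 181 lower in 20. The autosomal genes with the largest mean rise were Arc1 (mean log2 6.42), CG14695 (5.63), GstE6 (4.98), the cytochrome P450 gene Cyp6d2 (4.49) and nsr (3.85). Those with the largest mean fall were St2 (-5.31), lncRNA:CR44701 (-5.26), CG1273 (-3.11), CG9416 (-2.94) and Nep2 (-2.92). Fitted values of St2 in msl-1 and lncRNA:CR44701 in roX1 roX2 mutants enter these means although no reads were counted there, so that both means depend on the prior count. Of the 115 genes higher in 20 libraries 8 were X-linked, and of the 181 lower 95 were.

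The roX1 roX2 comparison shares its controls with the others. Of autosomal genes, 50 of 57 that were higher in msl-2 mutants were higher in roX1 roX2 mutants too, against 2.05 expected of independent lists, and 47 with separate controls. The shared number was 223 with msl-1 (47.7 expected of independent lists, 160 with separate controls) and 120 with mle (5.10 expected, 113 with separate controls). Autosomal genes lower in both numbered 30 with msl-2 (0.790 expected, 28 with separate controls), 116 with msl-1 (36.6 expected, 93 with separate controls) and 61 with mle (1.71 expected, 44 with separate controls). Lower X genes in both numbered 10, 39 and 33 with msl-2, msl-1 and mle (0.831, 16.8 and 4.72 expected). With separate controls they numbered 9, 40 and 18, against 0.626, 30.8 and 2.65 expected. The number shared with msl-1 was then much nearer to that of independent lists (Fisher exact p = 0.0329, against 6.86e-09 with shared controls). Higher X genes in both numbered 4, 12 and 6 (0.114, 2.03 and 0.205 expected; 4, 8 and 6 with separate controls). In 20 simulated datasets without any effect no gene was shared. At most 0.15 genes were called per comparison there on average, so that these datasets do not measure what shared controls add.

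Differences between the mutants were tested as differences of their effects. Dll fell more in msl-1 than in msl-2 mutants (difference 3.53 ± 0.45), and Rdh1 was higher in msl-1 than in msl-2 (difference -3.29 ± 0.33). roX1 fell further in mle than in msl-2 mutants by 4.53 ± 0.71. The effect on lncRNA:CR43144 was lower in mle than in msl-2 (by 5.66 ± 0.77), msl-1 (by 7.002 ± 0.79) and roX1 roX2 mutants (by 7.08 ± 0.66). The effect on CG12129 was lower in mle than in msl-2 (by 3.15 ± 0.47) and msl-1 mutants (by 3.55 ± 0.48). The translation factor gene mIF3 (3.91 ± 0.30 above msl-2) and ppk13 (7.03 ± 0.63 above mle) were higher in roX1 roX2 mutants, and CG11695 (-6.78 ± 0.55 against msl-2) and CR40190 (-7.22 ± 0.71 against msl-2) lower. The effect differed for 2997 genes between msl-2 and msl-1, 382 between roX1 roX2 and msl-1, 44 between roX1 roX2 and msl-2, 38 between roX1 roX2 and mle, 26 between msl-1 and mle and 3 between msl-2 and mle. In 20 libraries it differed for 1560, 775, 135, 81, 54 and 25 in that order. Across the 6 pairs 3112 genes differed, and 1855 in 20 libraries. That total was 864 without msl-1 mutant replicate 2 and 6313 without msl-1 heterozygous replicate 1. It was 1818 and 1979 without msl-1 mutant replicate 1 and 3, 2032 and 1587 without msl-2 mutant replicate 2 and 3, and 1306, 1560 and 2070 without msl-2 heterozygous replicate 1, 2 and 4.

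Measured against heterozygous discs, the X fell less relative to the autosomes in msl-2, msl-1 and roX1 roX2 mutants than in mle mutants, by 0.24, 0.46 and 0.32, and by 0.26, 0.23 and 0.24 in 20 libraries. Camera called these 3 differences (adjusted p = 6.66e-05, 6.66e-05 and 1.13e-09). With an estimated correlation adjusted p was 0.226, 0.226 and 0.137 over all 21 libraries and 0.000324, 0.00324 and 7.56e-05 in 20. The 3 other pairs differed by -0.21, 0.04 and -0.13, which camera did not call (adjusted p = 0.309 in each), and their signs turned in 20 libraries (0.05, -0.04 and 0.03). Directly between mutants, without the heterozygous discs, X minus autosome was 0.20 for msl-2 minus mle and 0.14 for roX1 roX2 minus mle, but -0.035 for msl-1 minus mle (unadjusted camera p across genes = 4.81e-05, 0.000879 and 0.347, with exact permutation p below). It was 0.21, -0.064 and 0.19 for msl-2 minus msl-1, roX1 roX2 minus msl-2 and roX1 roX2 minus msl-1 (unadjusted camera p across genes = 0.000203, 0.202 and 0.00108, with exact permutation p below). Thus over all 21 libraries 4 of the 6 pairs had the opposite sign, 2 of them with an unadjusted camera p under 0.05. In 20 libraries the direct values were 0.20, 0.14, -0.052, 0.23, -0.075 and 0.20 in that order. There msl-1 minus mle alone had the opposite sign (0.23 against heterozygous discs, -0.052 directly). The other turns of sign were present only with msl-1 heterozygous replicate 2 kept. Exact permutation p values between mutant libraries over the 6 pairs were 0.0286 for msl-2 against msl-1 and against mle (adjusted p = 0.0858), 0.114 for roX1 roX2 against msl-2 and 0.10, the smallest possible for 3 against 3, for the others. Without mle heterozygous replicate 1 or 2 the difference between msl-2 and mle was 0.18 or 0.17 (camera p = 0.0711 and 0.0848 across genes, with no exact test run on the difference of effects).

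The heterozygous groups differed from each other in 2914 genes over all 21 libraries and in 436 in 20. Cyp4p2, a cytochrome P450 gene, stood at 104 CPM in msl-1 heterozygous discs against 0.977 and 1.504 in msl-2 and mle heterozygous discs. CG3552 was at 63.5 CPM in msl-2 heterozygous discs against 10.7 in msl-1 and 12.9 in mle, and CR31054 at 36.3 against 0 in both. CG32373 was at 5.69 CPM in msl-2, 68.6 in msl-1 and 85.7 in mle heterozygous discs, and ppk13 at 0.742, 19.6 and 1.76. The count was 6313 without msl-1 heterozygous replicate 1, 295, 723 and 1064 without msl-2 heterozygous replicate 1, 2 and 4, and 797 and 996 without mle heterozygous replicate 1 and 2. The X stood lower in msl-1 heterozygous discs than in msl-2 heterozygous discs by 0.48 (log2), and by 0.24 in 20 libraries. In msl-2 heterozygous discs it differed from mle heterozygous discs by -0.02. Pair by pair, msl-2 and msl-1 heterozygous discs differed in 4841 genes (1076 in 20 libraries), msl-2 and mle in 33 (80) and msl-1 and mle in 10 (21).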

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

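All tests of explanations below were chosen after the result they measure was seen, except the test of the few X genes most changed. A library was singled out where it lay far from the others of a group of 4 to 10 libraries. Chance would single out about 1 in 20 independent groups, and here 11 of 64 did so, 10 of them in 1 library. The 64 are measures and genes read on the same 4 msl-2 mutant or 8 heterozygous libraries. They are not independent, so that rate does not apply to them.

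Heterozygous msl-1 replicate 2 stood far from the other 7 heterozygous libraries. Mitochondrial genes held 6.17% of its counts (1.13% to 2.54% in the others) and ribosomal RNA genes 0.0643% (0.000898% to 0.00807%), its X minus autosome value was -0.90 (-0.13 to 0.18), and roX1 was at 525.6 CPM (2626 to 3747). Genes low in the other heterozygous libraries were higher in it: Reepl1 at 8.22 CPM (0 to 1.93), Erk7 at 18.98 (0 to 3.86), OtopLa at 50.6 (2.59 to 10.6), lncRNA:CR44316 at 2.53 (0 to 0.6), CG31601 at 30.4 (0.879 to 10.1) and CG33509 at 25.9 (0.323 to 12.1). In roX1 roX2 mutants these 6 genes had means of 41.95 to 381 CPM. The genes checked here were those named for the roX1 roX2 comparison, so their high level in those mutants was fixed by that choice. It does not link the library to those mutants.

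Low depth was excluded as the cause of its X value: replicates 1 and 3 of its group, thinned in turn to the same total, had X minus autosome values of -0.149 to -0.0453 over 20 draws each, and median correlations of at least 0.939 with the other heterozygous libraries, against 0.509 for replicate 2. RNA of other cell types showed no sign of being the main source: 46 markers of other cell types that are weak elsewhere had 1.08 times the counts per kb of other weak genes (95% bootstrap interval 0.969 to 1.19). Most of these markers were germline and testis (14) or gut (13) genes. Fat body had 1 and hemocytes and trachea 2 each, too few to exclude RNA of those cells. Reads of genomic DNA may be the source: among protein-coding genes with a mean of at most 10 counts in the other libraries, X genes had 0.478 times the counts per kb of autosomal genes (0.442 to 0.511), near the ratio of X to autosome copies in males. At that rate background would fill 61.9% of the library, and the same ratio in the other libraries ran from 0.549 to 0.758.

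This test of genomic DNA was the second of its kind and its gene set was changed after the first had failed. The first used genes of any type with at most 10 counts over the other 20 libraries together (263 X and 1140 autosomal genes) and gave 1.81, outside its predicted range. The other libraries together gave 1.57 on those genes too, so that the set, chosen on that background, decides nothing. Ratios at limits of 10, 30, 60, 100 and 200 total counts were then looked at (1.81, 0.63, 0.506, 0.49 and 0.48 over all genes, and 5.69, 0.823, 0.545, 0.497 and 0.478 over protein-coding genes). The second set is the last of these, so it was chosen with its value in view. The ratio of 0.478 is therefore a hypothesis found on these data, and apart from RNA of other cell types no biological explanation of this library was tested.

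X-linked genes were lower in the mutants, the pattern the design asks about. Background reads that raise weakly expressed genes were excluded as the whole cause, since the X genes of the highest of 3 expression classes had a shift below 0 in 20 libraries, nearest to 0 at -0.34 in msl-2 (-0.68 in mle). The test of the few X genes most changed left out all called genes. Over genes not called the shift was still -0.23 in roX1 roX2, the nearest to 0, and -0.38 in mle, the farthest, in 20 libraries. A few genes hardly move a median, so the test shows that the shift reached genes not called and decides no more. Loss of dosage compensation may account for the shift, as the design names it, and that was not tested apart from the mutations (-0.34 and -0.23 above). A difference in larval age or growth between mutants and heterozygous siblings stays open.

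Genes changed the same way in all 4 mutants could reflect controls or balancer. In 20 libraries such genes lay on chromosome 2 about as often as on chromosome 3 (89 of 3931 against 95 of 4535, odds ratio 1.08, interval 0.799 to 1.47, Fisher exact p = 0.602). This argues against effects of the CyO balancer on genes of its own chromosome as the main source of the number of such genes. The count takes no account of size. Of the autosomal genes named for the largest mean rise, Arc1, GstE6, Cyp6d2 and nsr lie on 2R and CG14695 on 3R. Of those named for the largest mean fall, lncRNA:CR44701 and CG9416 lie on chromosome 2, and St2, CG1273 and Nep2 on chromosome 3. Over all 21 libraries the genes are too few to decide (35 of 4345 against 30 of 5043, odds ratio 1.36, interval 0.808 to 2.29). The sample titles name the balancer in every control and in no mutant. Its effects on genes of other chromosomes therefore cannot be told apart from those of the mutations. In single comparisons changed genes lay more often on chromosome 2 in roX1 roX2 (odds ratio 1.42, Fisher exact p = 0.000233, and 1.23 with p = 0.00272 in 20 libraries) and msl-2 mutants (1.56 with p = 0.021, and 8.55% of chromosome 2 against 7.34% of chromosome 3 genes in 20 libraries, p = 0.0434). A contribution of the balancer or of other chromosome 2 background therefore stays open there. Shared control libraries were excluded as the whole cause: between comparisons without a common library, autosomal genes called in both changed in the same direction in at least 91.7% of cases in each of the 6 pairs in 20 libraries (264 of 288 for msl-2 and msl-1, interval 87.9% to 94.6%). A response common to the mutants stays open as a hypothesis, as do a delay of development and a stock background that the mutants share.

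Other splits of the same libraries were counted for comparisons of at least 3 against 3, in a fit of those libraries alone. Its counts differ from the 138, 4360 and 609 genes reported for msl-2, msl-1 and roX1 roX2 and the 1490 of roX1 roX2 in 20 libraries, and chance was judged for the counts of that fit. For the 7 msl-2 libraries the real split gave 1218 genes, the only 1 of 35 to give as many, and the highest other 4. This argues against chance, at the lowest share that 35 splits allow. The shares were not adjusted for the number of comparisons. For the 6 msl-1 libraries the 10 splits are too few for a share under 0.05 (real 442, as many in 1 split, highest other 0). For roX1 roX2 with all 11 libraries chance could not be excluded: 8 of 100 splits gave as many as the real 165, the highest 2443, which points to a structure of the samples. In 20 libraries the real split gave 883 genes, as many in 1 of 100 splits, with the highest other at 76. These splits treat heterozygous libraries of 3 stocks as alike, although those differed in 436 genes in 20 libraries. They therefore measure stock as well as genotype.

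In msl-2 mutant replicate 2, CG11893 stood at 39.6 CPM, against 10.3 to 12.9 in the other three libraries of its group. Against heterozygous discs the X fell less than in mle mutants by 0.24 in msl-2, 0.46 in msl-1 (0.23 in 20 libraries) and 0.32 in roX1 roX2 mutants, by a test of the difference across genes that lost all 3 calls with an estimated correlation over all 21 libraries (adjusted p = 0.226, 0.226 and 0.137). Directly between mutants msl-1 minus mle was -0.035. Effects differed for 2997 genes between msl-2 and msl-1, 3 between msl-2 and mle, 26 between msl-1 and mle, and for 44, 382 and 38 between roX1 roX2 and msl-2, msl-1 and mle. In 20 libraries they differed for 1560, 25, 54, 135, 775 and 81 in that order. Genes with the smallest p for a difference of effects included Rdh1 (msl-2 minus msl-1 -3.29) and Dll (3.53), lncRNA:CR43144 (msl-1 minus mle 7.002, msl-2 minus mle 5.66) and CG12129 (3.55 and 3.15). Against roX1 roX2 they included ppk13 (roX1 roX2 minus mle 7.03), CG31601 (minus msl-1 8.96), mIF3 (minus msl-2 3.91) and CG11695 (-6.40 minus mle, -6.36 minus msl-1 and -6.78 minus msl-2). CG11695 lies beside roX2, and reach of the roX2 mutation into it was not tested.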

How the results depend on the processing

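Limma voom, DESeq2 and the replicate block in 20 libraries, and the stratified test with 1 library left out were alternatives chosen after the result was seen. So were the 20-library values of msl-2 and mle and of leading counts of the lists. For X minus autosome of each mutant alone, TMM on all genes and only the groups compared were also chosen after. The rest were fixed before the data were examined. The cause of each change below was not tested, except where fewer genes, libraries or controls are part of the alternative itself.

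X minus autosome stayed below 0 in msl-2 and mle mutants in every alternative run, but its size moved with the control. With all heterozygous groups as control it was -0.1986 in msl-2, -0.4517 in msl-1 and -0.4016 in mle (-0.3868, -0.1609 and -0.5803 in the main fit). In msl-1 it was 0.30 with no filter, 0.45 with a CPM of at least 1 in 3 libraries and 0.068 with the mean, and -0.14 with DESeq2, past the threshold no longer. In roX1 roX2 mutants it was 0.0196 with msl-1 heterozygous discs alone as control, and -0.4425 and -0.4176 with msl-2 and mle heterozygous discs alone (-0.2565 in the main fit). The values above 0 in msl-1 and roX1 roX2 mutants all include msl-1 heterozygous replicate 2. Contrasts taken directly between mutants gave 0.21 for msl-2 minus msl-1, -0.0353 for msl-1 minus mle, -0.064 for roX1 roX2 minus msl-2 and 0.19 for roX1 roX2 minus msl-1, each of the opposite sign over all 21 libraries. In 20 libraries msl-1 minus mle alone kept the opposite sign (-0.052 directly, 0.23 against heterozygous discs). Of genes named, 1 result changed sign after a call: Appl, roX1 roX2 mutant vs all heterozygous, was 0.0723 with msl-2 heterozygous discs alone as control.

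Counts of changed genes moved by more than 1.5 times as follows. No filter gave 87 in msl-2, 199 in mle and 1594 between heterozygous groups, and a CPM of at least 1 gave 239 in mle. All heterozygous groups as control gave 439 in msl-2, 1926 in msl-1 and 656 in mle. In roX1 roX2, msl-1 heterozygous discs alone gave 2013 and mle heterozygous discs alone 305. Only the groups compared gave 1218, 442, 829 and 273 in msl-2, msl-1, mle and roX1 roX2. Voom gave 2353, 1320 and 1793 in msl-2, mle and roX1 roX2, 5843 between mutants and 5543 between heterozygous groups. DESeq2 gave 359, 764 and 940 in msl-2, mle and roX1 roX2 and 4394 between heterozygous groups, and in 20 libraries 1160, 2427, 1466 and 1600 in msl-2, msl-1, mle and roX1 roX2.

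Replicate numbers did not pair the libraries (correlations of -0.29 to 0.23 between pairs of 1 number), so the block serves as an alternative alone. The block gave 87 in msl-2, 399 in roX1 roX2, 1529 between mutants and 195 between heterozygous groups, and in 20 libraries 884, 2067, 1298 and 1185 in msl-2, msl-1, mle and roX1 roX2.

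With 1 library left out, counts ran from 25 to 1108 in msl-2, 1696 to 6599 in msl-1, 30 to 1350 in mle and 262 to 1490 in roX1 roX2, from 864 to 6313 between mutants and from 295 to 6313 between heterozygous groups. X minus autosome ran from -0.40 to -0.36 in msl-2, -0.38 to -0.0323 in msl-1, -0.61 to -0.50 in mle and -0.35 to -0.20 in roX1 roX2, and the stratified value from -0.44 to -0.18. Between mutants it ran from -0.34 to 0.05 for msl-2 minus msl-1, 0.17 to 0.27 for msl-2 minus mle, 0.23 to 0.76 for msl-1 minus mle, -0.04 to 0.24 for roX1 roX2 minus msl-2, -0.33 to 0.03 for roX1 roX2 minus msl-1 and 0.24 to 0.35 for roX1 roX2 minus mle. Without msl-1 heterozygous replicate 2 the signs turned for msl-2 minus msl-1 (0.0514), roX1 roX2 minus msl-2 (-0.0371) and roX1 roX2 minus msl-1 (0.0312). A control left alone is assumed to vary like the other groups. Total counts of 830905 to 4131600 limit weakly expressed genes most.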

Other observations

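Signal of sex determination, neuronal, germline and Y-linked genes is given here for lists that the results above leave out. Sxl, the X-linked switch gene of sex determination, fell in msl-1 (-1.18 ± 0.24), mle (-1.21 ± 0.26) and roX1 roX2 mutants (-0.95 ± 0.21), and in 20 libraries in msl-2 mutants too (-0.58 ± 0.13). dsx fell in msl-1 mutants (-1.41 ± 0.24). Of 8 sex determination genes 0, 2, 1 and 1 fell in msl-2, msl-1, mle and roX1 roX2, and 0, 2, 2 and 1 adjusted over the list alone, with 1 higher in roX1 roX2. In 20 libraries 1, 2, 1 and 1 of 7 fell. Of 16 genes of neurons and glia 11 fell in msl-1, with brp (-3.23 ± 0.61), a scaffold of synaptic active zones, and Syt1 (-2.75 ± 0.56), a calcium sensor of vesicle release (12 fell and 1 rose adjusted over the list alone, camera adjusted p = 0.00504, and 0.602 with an estimated correlation), and 5 in 20 libraries. Appl rose in mle (1.41 ± 0.30) and fell in roX1 roX2 mutants (-0.83 ± 0.24), the single call of the list in each, over all genes and adjusted over the list alone, and none passed in msl-2, where 1 rose in 20 libraries. The fall of Appl in roX1 roX2 mutants turned to a small rise with msl-2 heterozygous discs alone as control. Of 16 germline and testis genes 10 fell in msl-1, 13 adjusted over the list alone, with piwi (-1.73 ± 0.35), a gene of transposon silencing, and tj (-3.15 ± 0.84); camera adjusted p was 0.00356, and 0.602 with an estimated correlation, and 3 of 11 fell in 20 libraries. None passed in the other three comparisons. Of 12 Y-linked genes 5 fell in msl-1, 1 rose in roX1 roX2 and none passed in msl-2 and mle, with the same numbers adjusted over the list alone (camera higher in msl-2, adjusted p = 0.0414, and 0.963 with an estimated correlation). kl-5 (-2.84 ± 0.84), a dynein gene of sperm tails, did not pass in 20 libraries (-1.12 ± 0.71), where 1 of 8 fell in msl-1. In 20 libraries brp (-2.03 ± 0.47), Syt1 (-1.63 ± 0.45) and tj (-2.26 ± 0.76) fell by less in msl-1.

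Among genes of metabolism, oxidative phosphorylation had 7 of 70 genes higher and 3 lower in msl-1 mutants, with Cyt-c1 (1.94 ± 0.44) and UQCR-C1 (1.39 ± 0.43) of respiratory complex III, and 2 higher adjusted over the list alone. COX7AL rose in mle (4.76 ± 0.98) and roX1 roX2 mutants (3.65 ± 0.55), the single call in each, also adjusted over the list alone. Camera called this list lower in msl-2 (adjusted p = 0.000252) and mle (0.00876) and higher in msl-1 (6.72e-07), and none of these held with an estimated correlation (adjusted p = 0.963, 0.907 and 0.602). In 20 libraries 15 fell in msl-2, 14 in mle and 9 in roX1 roX2. Of 78 genes of the cytoplasmic ribosome RpLP0-like rose in msl-1 (1.42 ± 0.41) and no other passed in any comparison, with 0 adjusted over the list alone. Camera called this list lower in msl-2 (adjusted p = 0.0263) and mle (0.0192) and higher in msl-1 (1.10e-06), none with an estimated correlation (adjusted p = 0.963, 0.907 and 0.616), and in 20 libraries, of 77 tested, 3, 14 and 5 fell in msl-2, mle and roX1 roX2 and 2 rose and 1 fell in msl-1. Of 12 glycolysis genes 4 rose in msl-1, with Ldh (2.88 ± 0.54) and Gapdh1 (1.24 ± 0.47), 1 adjusted over the list alone (camera adjusted p = 0.00284, and 0.602 with an estimated correlation), and none in the other three comparisons, where camera called the list higher in roX1 roX2 (adjusted p = 0.0319, and 0.868 with an estimated correlation). In 20 libraries 2 glycolysis genes rose in msl-1 and in roX1 roX2 and 2 fell in msl-2. Of 34 cell cycle genes 6 rose in msl-1 and 1 in roX1 roX2, with RnrL, a subunit of ribonucleotide reductase, in each (1.93 ± 0.33 and 0.96 ± 0.26). Adjusted over the list alone 2 rose in msl-1, 1 in roX1 roX2 and 1 in msl-2, and camera adjusted p was 0.00284 in msl-1 and 0.0286 in roX1 roX2 (0.616 and 0.868 with an estimated correlation). In 20 libraries 2, 2, 2 and 3 rose and 1, 2, 1 and 2 fell in msl-2, msl-1, mle and roX1 roX2.

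Of 18 chromatin factors linked to dosage compensation 5 rose in msl-1, also 5 adjusted over the list alone, with Pof (1.05 ± 0.22), whose protein coats the fourth chromosome, and Rcd5 (1.17 ± 0.32) of the NSL complex (camera adjusted p = 0.00356, and 0.610 with an estimated correlation; 2 rose and 1 fell in 20 libraries), and none passed elsewhere over all 21 libraries. In 20 libraries 1, 2 and 2 rose and 1 fell in each of msl-2, mle and roX1 roX2. Of 14 autosomal pericentric genes vtd rose in msl-1 (0.83 ± 0.22) and lt in mle (1.24 ± 0.24), and 2 rose in roX1 roX2 in 20 libraries. Adjusted over the list alone 1 rose in each of msl-1, mle and roX1 roX2 (camera adjusted p = 0.00378 in msl-1 and 0.0128 in roX1 roX2, and 0.602 and 0.868 with an estimated correlation). Of 20 genes of heat shock and unfolded protein response Xbp1 (1.00 ± 0.36) and crc (1.17 ± 0.46) rose in msl-1, Xbp1 not past the threshold in 20 libraries (0.56 ± 0.23; camera adjusted p = 0.00743, and 0.602 with an estimated correlation), and adjusted over the list alone 3 rose and 1 fell in msl-2 and 0 in the others. In 20 libraries 1, 2, 1 and 0 rose and 4, 2, 3 and 3 fell in msl-2, msl-1, mle and roX1 roX2. Of 12 immunity genes Tep4 (1.62 ± 0.23) and PGRP-SA (2.03 ± 0.60) rose and Tep1 (-2.20 ± 0.55, and -1.40 ± 0.49 in 20 libraries) fell in msl-1, and the stress-induced TotA (6.87 ± 1.23) and TotC (5.21 ± 1.07) rose in roX1 roX2, with the same numbers adjusted over the list alone and none in msl-2 and mle; of 6 tested in 20 libraries 1 rose in msl-2 and none passed in roX1 roX2. Apoptosis genes had no call in msl-2 and roX1 roX2 mutants, and leg and haltere genes none in msl-2, over all genes and adjusted over the list alone. In 20 libraries 2 apoptosis genes rose and 2 fell in roX1 roX2.

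Most lower calls among markers of other tissues were in msl-1 over all 21 libraries, where 25.4% of all genes tested were lower (0.648%, 1.97% and 1.93% in msl-2, mle and roX1 roX2), and no excess of markers over that share was tested. Of 12 genes of adult muscle precursors 3 fell and 1 rose in msl-1, with sns (-2.45 ± 0.33), and 2 fell in roX1 roX2, with the same numbers adjusted over the list alone, and in mle 1 fell adjusted over the list alone and 2 in 20 libraries (camera adjusted p = 0.0211 in mle, and 0.298 with an estimated correlation). Larval muscle had 4 of 19 lower in msl-1, 2 adjusted over the list alone and 0 in 20 libraries, with Act88F (-2.84 ± 0.78), and none in mle and roX1 roX2. Fat body had 2 of 12 lower in msl-1, also 2 adjusted over the list alone, with GLaz (-2.86 ± 0.55), 1 in 20 libraries, and none in mle and roX1 roX2. Hemocytes had 3 of 12 lower in msl-1, 2 adjusted over the list alone, with NimC2 (-3.32 ± 0.94, and -1.58 ± 0.83 in 20 libraries, not past the threshold; 1 of 11 in 20 libraries), and none elsewhere. Trachea had 3 of 10 higher and 3 lower in msl-1, also 3 and 3 adjusted over the list alone, and obst-A fell in mle (-2.55 ± 0.57); adjusted over the list alone 2 fell in mle and 1 in roX1 roX2. In 20 libraries 1, 2, 3 and 2 of 9 fell in msl-2, msl-1, mle and roX1 roX2 and none rose. Salivary gland had 3 of 6 lower in msl-1, also 3 adjusted over the list alone, with fkh (-2.64 ± 0.76), and none elsewhere. Cuticle had 4 of 17 higher and 1 lower in msl-1, 3 and 1 adjusted over the list alone, with Gasp (1.47 ± 0.53), and none elsewhere, and none in 20 libraries in msl-1. In the gut list LManII fell in msl-2 (-1.98 ± 0.37), msl-1 (-1.69 ± 0.43) and mle (-2.46 ± 0.45), with Mal-A1 in msl-1 (-3.08 ± 1.11); adjusted over the list alone 1 fell in each of the 3.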
